A study of Mus musculus with 12 samples.

How the data were processed

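Total RNA from mouse hippocampal tissue was sequenced in 12 libraries, 4 in each of 3 groups named FMT-CON, FMT-DSS and FMT-SP in the sample labels. The deposited file holds 1 value per gene and library in FPKM (fragments per kilobase of transcript per 1000000 mapped fragments), computed by the authors. The labels name HISAT2 2.0 and the genome build mm8 without saying what each was used for. The read counter, the annotation behind the values and any filter of the authors are not given in the sources used here. The file has 27978 genes, of which 0 are at 0 in every library, and 0 pairs of libraries are identical. Groups and replicate numbers were taken from the sample titles.

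Read totals were not used here, and depth was estimated from the values. In genes with a single annotated transcript (4803 genes of the GENCODE vM21 annotation of GRCm38), low FPKM values lie on steps of 1 fragment, and the step size gives the total of mapped fragments in a library. Between 37.2% and 39.3% of the low values lay within 0.05 of a whole number of fragments, against 10% by chance. The estimates run from 31.5 M (M, 1000000 mapped fragments) in FMT-DSS 3 to 37.0 M in FMT-DSS 2, a ratio of 1.18. At those totals, 1 fragment in a transcript of 2000 bases equals 0.0135 to 0.0159 FPKM, and a transcript of that length at 1 FPKM rests on 62.9 to 74.1 fragments. The annotation also gave gene positions, matched by symbol for 21378 genes.

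Values were tested as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 12 libraries were kept, which left 12559. All libraries were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The 3 comparisons were FMT-DSS against FMT-CON, FMT-SP against FMT-DSS and FMT-SP against FMT-CON, each two-sided. Changes are on the log2(FPKM + 1) scale with the standard error from the model, and levels are mean FPKM ± SD with n = 4 libraries. The labels do not say whether each library is a separate animal, so p-values of single genes and of list means per library measure only the spread between these samples.

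Gene lists for 48 pathways, cell types and neighbouring brain regions were fixed before the data were examined. The 45 lists with at least 4 tested members were compared with all other tested genes by camera in limma, with a preset correlation between genes of 0.01, and adjusted over the 45 lists of a comparison. Camera with the correlation estimated from the data and the rotation test fry were run beside it. The preset treats list members as nearly independent, while the estimated correlation had a median of 0.38 over the lists. Camera p-values with the preset therefore do not measure the spread of a list mean between libraries. The mean of each list per library, centred per gene, was also compared by an exact permutation test over the 70 assignments of 8 libraries, whose smallest p is 0.0286. Counts called adjusted over the list alone use the members of 1 list as the family of tests. The genes to name were fixed by a rule before the data were examined: genes past the threshold with non-overlapping groups, or, where fewer than 10 passed, the 10 of smallest unadjusted p, leaving out symbols without a gene name; Tac1, Tac2 and Tacr1 in every comparison; and up to 4 members of smallest p from each list described. Some members that the rule selects are not reported here, though list tests and counts include them. The 5 lists described per comparison are those of smallest camera p, a number chosen after the results were seen.

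Whether FMT-SP reversed the FMT-DSS values was examined by the overlap and the correlation of fold changes between FMT-DSS against FMT-CON and FMT-SP against FMT-DSS. Both comparisons use the same 4 FMT-DSS libraries, which alone gives a negative correlation. The correlation was therefore also computed with the FMT-DSS libraries divided over the 6 possible splits, with 100 relabellings of the libraries, and with 20 simulations without any group effect.

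The model was tested on simulated data with the means and spreads of these libraries, with 200 changed genes and each gene drawn independently of the others. It called 40% of 1.5-fold changes, 87% of 2-fold changes and 99.5% of 4-fold changes in FMT-DSS against FMT-CON, and 44%, 86% and 98.5% in FMT-SP against FMT-DSS. These folds are of FPKM + 1, so in genes of low level they stand for larger folds in FPKM. A list shifted by 0.5 in simulation was called by camera at an adjusted p of 1.92e-08, with 0 other lists called. That simulation had no correlation between genes, so it gives no rate of false list calls for these libraries. In the real libraries, splits of a comparison into 4 and 4 other than by group gave a median of 12, 12 and 12.5 lists called.

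The alternatives were a pseudocount of 0.1, a filter at a mean of 0.1 FPKM and no filter, 3 rescalings (each library to a sum of 1000000, median ratios, quantiles), robust empirical Bayes, array weights, a model of the 2 compared groups only, replicate numbers as a block, a 1.5-fold minimum and leaving out each library in turn. After the data were seen, 4 more were added: marker means of choroid plexus and striatum as 2 covariates, removal of the 3 libraries numbered 4, removal of FMT-DSS 2 and FMT-DSS 4, and removal of the libraries highest in thalamus, striatum and pituitary markers. Transcript isoforms, splicing and variants were left out because the file holds 1 value per gene. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.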

Results

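The data are RNA-seq gene levels of mouse hippocampal tissue taken after fecal microbiota transplantation. There were 12 libraries, 4 each from FMT-CON, FMT-DSS and FMT-SP, the last named FMT-DSS+SP in the description of the series, where SP is the neuropeptide substance P. What CON and DSS stand for is not given in the labels, nor is the step of the experiment at which substance P was given, or to which animals. Levels are in FPKM as deposited, and no untransplanted mice are among the samples. The estimated depth, in M (1000000) mapped fragments, was 36.3, 36.6, 36.1 and 34.9 M in FMT-CON 1 to 4, 36.6, 37.0, 31.5 and 34.5 M in FMT-DSS 1 to 4, and 36.2, 33.4, 36.7 and 33.7 M in FMT-SP 1 to 4.

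Several libraries stood apart in markers of tissue next to the hippocampus, in genes picked after their values were seen. Ttr, the transthyretin gene that marks choroid plexus, ranged from 14.7 to 3779 FPKM, and within FMT-CON its highest value was 131 times its lowest. Ppp1r1b, a marker of striatum, reached 140 FPKM in FMT-DSS 3, and Tcf7l2, a marker of thalamus, 17.7 FPKM in FMT-CON 1. The pituitary hormone genes Gh and Prl were at 2899 and 621 FPKM in FMT-CON 3. Hbb-bs, a hemoglobin gene, was highest in FMT-SP 2 at 682 FPKM. The 3 libraries numbered 4 had 27.7%, 29.0% and 24.0% of their FPKM in mitochondrially encoded genes, against 15.9% to 20.3% in the other 9.

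**Figure D1:**
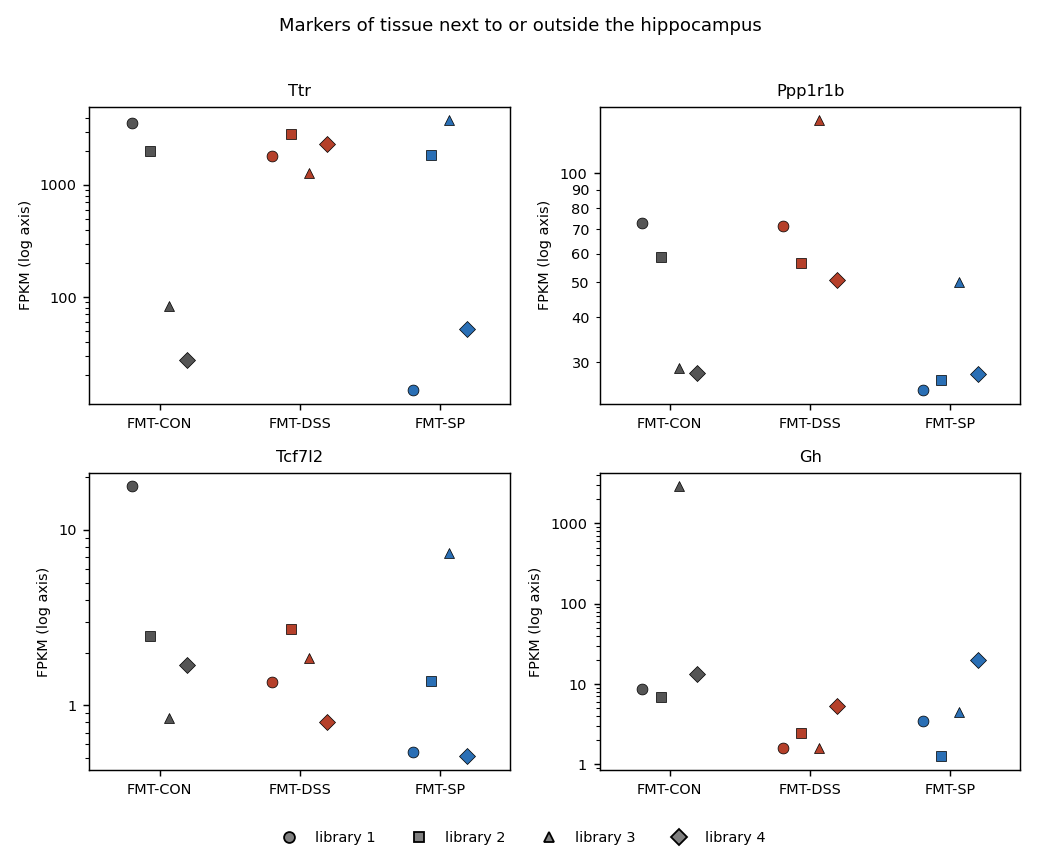
FPKM of Ttr, Ppp1r1b, Tcf7l2 and Gh in each library (points, marked by library number) on log axes, by group. Ttr spans 14.7 to 3779 FPKM over the libraries, and Gh reaches 2899 FPKM in FMT-CON 3.

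FMT-DSS against FMT-CON asks how the hippocampus of mice given FMT-DSS material differed from that of FMT-CON mice. All 15 glucocorticoid-responsive genes tested, which stress hormones induce through the glucocorticoid receptor, had higher means in FMT-DSS. Their average was 0.67 higher on the log2 scale (list mean 0.44 ± 0.39 SD in FMT-DSS and -0.22 ± 0.26 in FMT-CON, n = 4 each). The library means were uneven, at 0.89 and 0.63 in FMT-DSS 2 and FMT-DSS 4 and at 0.05 and 0.20 in FMT-DSS 1 and FMT-DSS 3. Fkbp5, a chaperone of that receptor on chromosome 17 (28399094 to 28517527, GRCm38), was at 29.4 ± 7.87 FPKM in FMT-DSS and 18.3 ± 1.05 in FMT-CON, a log2 change of 0.63 ± 0.18. Sgk1, a kinase gene induced by corticosteroids, was at 47.0 ± 8.38 and 27.0 ± 11.99 FPKM, and Pdk4, which restrains the use of pyruvate in mitochondria, at 4.73 ± 0.808 and 2.62 ± 0.843. In the opposite direction, all 12 microglia markers tested had lower means in FMT-DSS, with list means of -0.86 and -0.91 in FMT-DSS 2 and FMT-DSS 4. Erythrocyte markers were high in the same libraries, at 0.93 and 1.19.

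No single gene passed limma's test over all genes in this comparison: 0 of 12559 genes had an adjusted p under 0.05, and the smallest was 0.966. At an unadjusted p under 0.05 there were 510 genes, 157 higher and 353 lower, where chance gives 628; the count was 243 without FMT-DSS 2, 855 without FMT-DSS 1, 1198 without FMT-DSS 3 and 162 without both FMT-DSS 2 and FMT-DSS 4. Median-ratio rescaling, which pulls the median change towards 0 by construction, gave 241 higher and 243 lower, and quantile normalization 216 and 284. With choroid plexus and striatum marker means as covariates, added after the data were seen, the count was 1745 (452 higher, 1293 lower). Other splits of these libraries into 4 and 4, without covariates, gave up to 3885, a reference for the 510 and not for the 1745. The groups did not overlap in 220 genes (1.75%, with 2.86% by chance). The 95% interval of the change had a median half-width of 0.31 on the log2(FPKM + 1) scale. It lay within 2-fold of FPKM + 1 for 95.9% of genes, which at low levels does not bound the change in FPKM to 2-fold.

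The gene of smallest p was Camk1, a calcium and calmodulin dependent kinase gene on chromosome 6 (113334124 to 113343984), at 20.2 ± 1.60 FPKM in FMT-DSS and 28.2 ± 3.79 in FMT-CON, a log2 change of -0.46 ± 0.10. Grm2, a glutamate receptor that restrains transmitter release, on chromosome 9 (106643095 to 106656082), was at 13.6 ± 3.63 and 22.0 ± 3.44 FPKM, a change of -0.68 ± 0.17. Klf15, a transcription factor gene on chromosome 6 (90462576 to 90475238), was at 6.77 ± 1.47 and 4.06 ± 0.579 FPKM, a change of 0.60 ± 0.16. Tmem141, Serf1, Gmds, Pigbos1, Mrps36 and Serpinf1 had changes of -0.43, -0.61, -0.40, -0.68, -0.40 and -0.41, and Tmem215 one of 0.40. In 9 of these 10 genes the 4 libraries of the groups did not overlap (exact permutation p = 0.0286, the smallest possible), and Pigbos1 overlapped. Since the 10 were picked by smallest p in the same libraries, that separation is no further support.

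By camera, 11 of 45 lists passed, 6 higher and 5 lower in FMT-DSS, and 0 passed with an estimated correlation or by fry. The glucocorticoid-responsive list had an adjusted p of 2.59e-16, and adjusted p = 0.292 with an estimated correlation; the exact permutation p of its mean was 0.0286, or 0.643 adjusted over the lists. Of its 15 members, 0 passed over all genes and 7 passed adjusted over the list alone: Fkbp5, Pdk4, Sgk1, Ddit4, Per1, Cdkn1a and Nfkbia, all higher. That count of 7 fell to 0 without FMT-CON 2, FMT-CON 4, FMT-DSS 2 or FMT-DSS 4 and to 1 without FMT-SP 1, while camera kept the call without any 1 library. Without both FMT-DSS 2 and FMT-DSS 4, the list average was 0.35 (adjusted p of 9.56e-06) and the count 0. Ddit4, a stress-induced inhibitor of mTOR signalling, was 0.76 ± 0.25 higher, and Per1, a clock gene that also responds to glucocorticoids, 0.62 ± 0.21. Cdkn1a, which encodes a brake on the cell cycle, reached 63.2 and 69.0 FPKM in FMT-DSS 2 and FMT-DSS 4 and lay between 5.75 and 16.7 in the other 10 libraries.

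The microglia markers averaged -0.51 (list means -0.34 ± 0.63 and 0.17 ± 0.15, n = 4), with an adjusted p of 5.55e-05 by camera and adjusted p = 0.686 with an estimated correlation. The low values lay in FMT-DSS 2 and FMT-DSS 4. Cx3cr1, a chemokine receptor of microglia, was at 1.12 and 2.20 FPKM there and between 7.37 and 13.9 in the other 10 libraries. Without FMT-DSS 2 the average was -0.34 and without FMT-DSS 4 it was -0.32, with adjusted p of 7.08e-04 and 0.0279, and it was -0.25 with array weights. Without both, the average turned to 0.03 and the call was lost (adjusted p of 0.417). Siglech, Tmem119, Aif1 and Olfml3, further microglial genes, had changes of -0.57, -0.57, -0.55 and -0.79, none past the test over all genes. C1qa, a complement gene of microglia chosen here after its values were seen, was at 59.2 FPKM in FMT-DSS 2, its highest value among the 12 libraries, and at 36.7 in FMT-DSS 4. In the same FMT-DSS 2 library, Lcn2, a gene of reactive astrocytes likewise picked afterwards, reached 285 FPKM.

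The circadian clock list had 12 of 16 members higher and 4 lower, with a mean of 0.19, an adjusted p of 2.70e-04 and adjusted p = 0.471 with an estimated correlation. Ciart, a repressor in the clock, had a change of 0.85, Cry2 of 0.34 and Tef of 0.24, and Per1 belongs to the glucocorticoid list as well. Ciart was at 15.4 and 16.8 FPKM in FMT-DSS 2 and FMT-DSS 4, at 4.64 and 7.29 in FMT-DSS 1 and FMT-DSS 3 and between 3.41 and 6.36 in FMT-CON. With FMT-DSS 2 and FMT-DSS 4 removed, the change of Ciart was 0.19 and that of Cry2 0.22, while camera kept the list (mean 0.15, adjusted p of 0.00278). All 5 erythrocyte markers had higher means (1.07 on average, adjusted p of 7.42e-04, adjusted p = 0.686 with an estimated correlation), with Alas2 at 1.10, Hbb-bt at 1.19, Hba-a1 at 1.07 and Hbb-bs at 1.03. Array weights ended that call at an adjusted p of 0.290, and removal of FMT-DSS 2 and FMT-DSS 4 at 0.165 (mean 0.55). All 8 markers of CA1 pyramidal cells had higher means (0.29 on average, adjusted p of 0.00120, adjusted p = 0.686 with an estimated correlation), among them Itpka at 0.48, Fibcd1 at 0.40, Spink8 at 0.52 and Pou3f1 at 0.24. The CA1 call was lost without FMT-CON 1 (mean 0.10, adjusted p of 0.171) with array weights (0.0544) and without FMT-DSS 2 and FMT-DSS 4 (mean 0.16, 0.113).

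The other 6 lists called did not hold throughout. Cholesterol synthesis (14 of 17 members lower, adjusted p of 0.00631) had 0.385 without FMT-DSS 4. The markers of dentate granule cells (11 of 12 lower, 0.0242) had 0.163 without FMT-DSS 2, and those of choroid plexus (12 of 13 higher, 0.0261) had 0.429 without FMT-CON 4. The unfolded protein response (12 of 14 lower, 0.0306) had 0.157 without FMT-DSS 4. Hypothalamus and pituitary markers (5 of 6 lower, 0.0324) had 0.153 without FMT-DSS 1, and their mean of -1.53 became -0.62 without FMT-CON 3. Reactive astrocyte genes (8 of 9 higher, 0.0486) had 0.943 without FMT-DSS 2, with a mean of -0.02. With an estimated correlation, the 11 called lists had adjusted p = 0.292 to 0.864. The other 34 lists had adjusted p between 0.0875 and 0.957. In them, the NF-kB targets had 2 members that passed adjusted over the list alone, Icam1 (1.24 ± 0.46) and Nfkbia, which the glucocorticoid list also holds; the glutamate receptors had Grm2, and the adult neurogenesis genes had Hes5 (-0.58 ± 0.18); each of these counts was 0 without FMT-CON 1, FMT-CON 4, FMT-DSS 2 or FMT-DSS 4, among others. Mean, median and test differed in sign for NF-kB targets, microglia activation, glutamate receptors, monoamine receptors, tryptophan metabolism, antioxidant genes, apoptosis, astrocyte, oligodendrocyte precursor and ependymal markers.

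**Figure D2:**
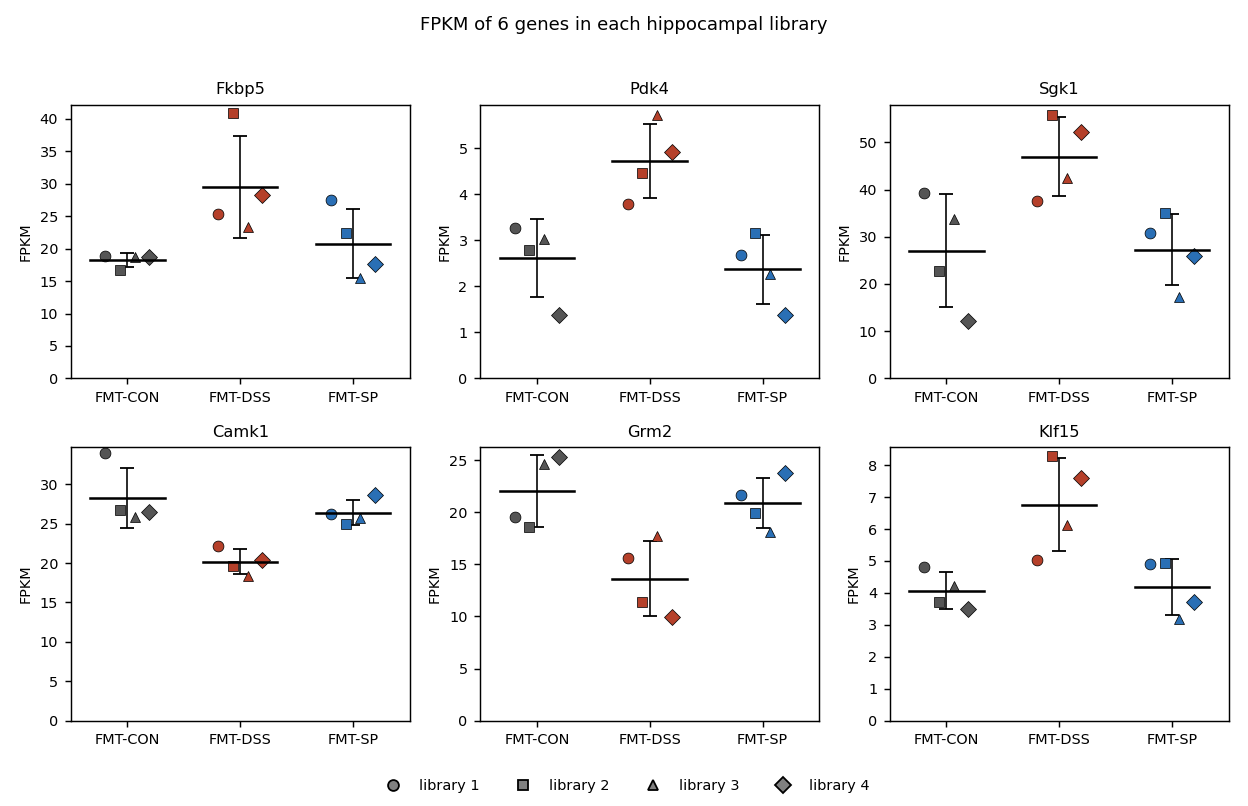
FPKM of Fkbp5, Pdk4, Sgk1, Camk1, Grm2 and Klf15 in each library (points, marked by library number), with the group mean and SD as bars, n = 4. Camk1 averages 28.2, 20.2 and 26.4 FPKM, and Pdk4 2.62, 4.73 and 2.37 FPKM, in FMT-CON, FMT-DSS and FMT-SP.

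FMT-SP against FMT-DSS asks how hippocampal gene levels of the group with substance P differed from those of FMT-DSS. The 15 glucocorticoid-responsive genes all had lower means in FMT-SP, by an average of -0.66, which left the list mean at -0.22 ± 0.31 (SD, n = 4), close to that of FMT-CON. All 12 microglia markers had higher means, by 0.51 on average. This comparison and FMT-DSS against FMT-CON share the 4 FMT-DSS libraries. Lists high or low in those libraries therefore tend to move back here without any reversal. The division of these libraries between the comparisons was run across genes only, not for single lists. Pdk4, on chromosome 6 (5483351 to 5496309), was at 2.37 ± 0.757 FPKM in FMT-SP and 4.73 ± 0.808 in FMT-DSS, a log2 change of -0.78 ± 0.21. Camk1 was at 26.4 ± 1.59 FPKM in FMT-SP, 0.37 ± 0.10 above FMT-DSS.

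Limma gave 0 of 12559 genes past the threshold, with a smallest adjusted p of 0.999. There were 314 genes at an unadjusted p under 0.05 (159 higher, 155 lower, 628 by chance). That count was 149 without FMT-DSS 4, 159 without FMT-DSS 2, 798 without FMT-DSS 1 and 794 without FMT-DSS 3 (550 higher, 244 lower). Without both FMT-DSS 2 and FMT-DSS 4 it was 105 (22 higher, 83 lower). It was 2236 (1563 higher, 673 lower) with the marker covariates added after the data were seen. Other splits of these libraries into 4 and 4, without covariates, gave up to 2432, a reference for the 314 and not for the 2236. There were 160 genes with groups that did not overlap (1.27%, with 2.86% by chance). The gene of smallest p was Rela, the p65 subunit of NF-kB, on chromosome 19 (5637483 to 5648130), at 5.72 ± 0.357 FPKM in FMT-SP and 8.38 ± 0.961 in FMT-DSS, a change of -0.48 ± 0.11. Ikbkg, a regulator of the kinase that activates NF-kB, had a change of -0.69 and Nt5e, which makes adenosine outside cells, one of -0.51. Grm2 was at 20.9 ± 2.42 FPKM in FMT-SP, a change of 0.61, and Klf15 at 4.19 ± 0.884, a change of -0.58. Chia1, Spsb1 and Lingo3 had changes of -0.55, -0.57 and -0.40. All 10 of these genes had groups that did not overlap (exact permutation p = 0.0286, the smallest possible), and none passed the test over all genes. Since the 10 were picked by smallest p in the same libraries, that separation is no further support.

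Camera called 18 of 45 lists, 6 higher and 12 lower in FMT-SP, and 0 passed with an estimated correlation or by fry. The glucocorticoid-responsive list had an adjusted p of 4.24e-17 and adjusted p = 0.234 with an estimated correlation; the exact permutation p of its mean was 0.0286, or 0.429 adjusted over the lists. Of its members, 0 passed over all genes and 3 passed adjusted over the list alone: Pdk4, Per1 (-0.67 ± 0.21) and Cdkn1a (-1.60 ± 0.50), all lower. The count of 3 was 0 without FMT-CON 3, FMT-DSS 2, FMT-DSS 4, FMT-SP 3 or FMT-SP 4, 5 without FMT-DSS 3 and 9 without FMT-DSS 1. Camera kept the call without any 1 library, and the list average was -0.38 with array weights and -0.34 without both FMT-DSS 2 and FMT-DSS 4 (adjusted p of 6.23e-07). Fkbp5 was at 20.8 ± 5.33 FPKM in FMT-SP, a change of -0.48 ± 0.18.

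The microglia list had an adjusted p of 1.64e-06 and adjusted p = 0.613 with an estimated correlation. Cx3cr1 had a change of 1.11, P2ry13 of 0.70, Tmem119 of 0.57 and Siglech of 0.45, and the average was 0.34 without FMT-DSS 2, 0.32 without FMT-DSS 4 and 0.21 with array weights. Without both FMT-DSS 2 and FMT-DSS 4 it turned to -0.03 and the call was lost (adjusted p of 0.581). Of the 16 circadian clock genes, 13 had lower means (-0.23 on average, adjusted p of 1.01e-05, adjusted p = 0.234 with an estimated correlation), with Ciart at -0.99, Dbp at -0.41 and Cry2 at -0.23. With FMT-DSS 2 and FMT-DSS 4 removed, Ciart was at -0.33 and Cry2 at -0.11, and camera kept the list (mean -0.19, adjusted p of 4.62e-05). All 10 striatum markers had lower means (-0.69 on average, adjusted p of 1.01e-05, adjusted p = 0.649 with an estimated correlation). Ppp1r1b, which encodes a dopamine-regulated phosphatase inhibitor, had a change of -1.21 ± 0.37, with Penk at -0.87, Pde10a at -0.51 and Rasd2 at -0.46. The striatum call was lost without FMT-DSS 3, the library highest in Ppp1r1b (mean -0.21, adjusted p of 0.0665), and the mean was -1.32 with array weights and -1.65 without FMT-DSS 2 and FMT-DSS 4. In cholesterol synthesis 16 of 17 genes had higher means (0.22 on average, adjusted p of 0.00105, adjusted p = 0.691 with an estimated correlation), with Sqle at 0.38, Hmgcs1 at 0.32 and Dhcr7 at 0.19. That call was lost without FMT-DSS 4 (mean 0.07, adjusted p of 0.186) and with array weights (0.249), and the mean turned to -0.07 without both FMT-DSS 2 and FMT-DSS 4 (adjusted p of 0.0672).

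The other 13 lists called were each lost without at least 1 library. Those lower in FMT-SP were reactive astrocyte genes (8 of 9 members, adjusted p of 0.00105, 0.324 without FMT-DSS 2), choroid plexus markers (12 of 13, 0.00218, 0.214 without FMT-SP 4) and ependymal markers (9 of 9, 0.00906, 0.198 without FMT-SP 4). Ribosomal proteins (23 of 26, 0.0116) and mitochondrially encoded genes (11 of 13, 0.0466) had 0.940 and 0.629 without FMT-DSS 4, where both means turned to 0.01. Antigen presentation (8 of 8, 0.0181) and complement (6 of 7, 0.0466) had 0.771 and 0.646 without FMT-DSS 2, where the complement mean turned to 0.06. Immediate early genes (10 of 17, 0.0427) had 0.536 without FMT-DSS 3, and erythrocyte markers (5 of 5, 0.0427) had 0.419 without FMT-SP 1. Those higher in FMT-SP were dentate granule cell markers (10 of 12, 0.00717, 0.113 without FMT-DSS 2), the neurotrophin system (7 of 7, 0.0244, 0.122 without FMT-DSS 3), GABA receptors (12 of 14, 0.0258, 0.629 without FMT-DSS 4) and adult neurogenesis genes (6 of 7, 0.0322, 0.181 without FMT-DSS 2). With an estimated correlation, the 18 called lists had adjusted p = 0.234 to 0.784. The other 27 lists had adjusted p between 0.0569 and 0.939. Mean, median and test differed in sign for NF-kB targets, microglia activation, nuclear oxidative phosphorylation, tryptophan metabolism, nuclear-retained long noncoding RNAs, astrocyte, oligodendrocyte precursor, meningeal, thalamus, and hypothalamus and pituitary markers.

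**Figure D3:**
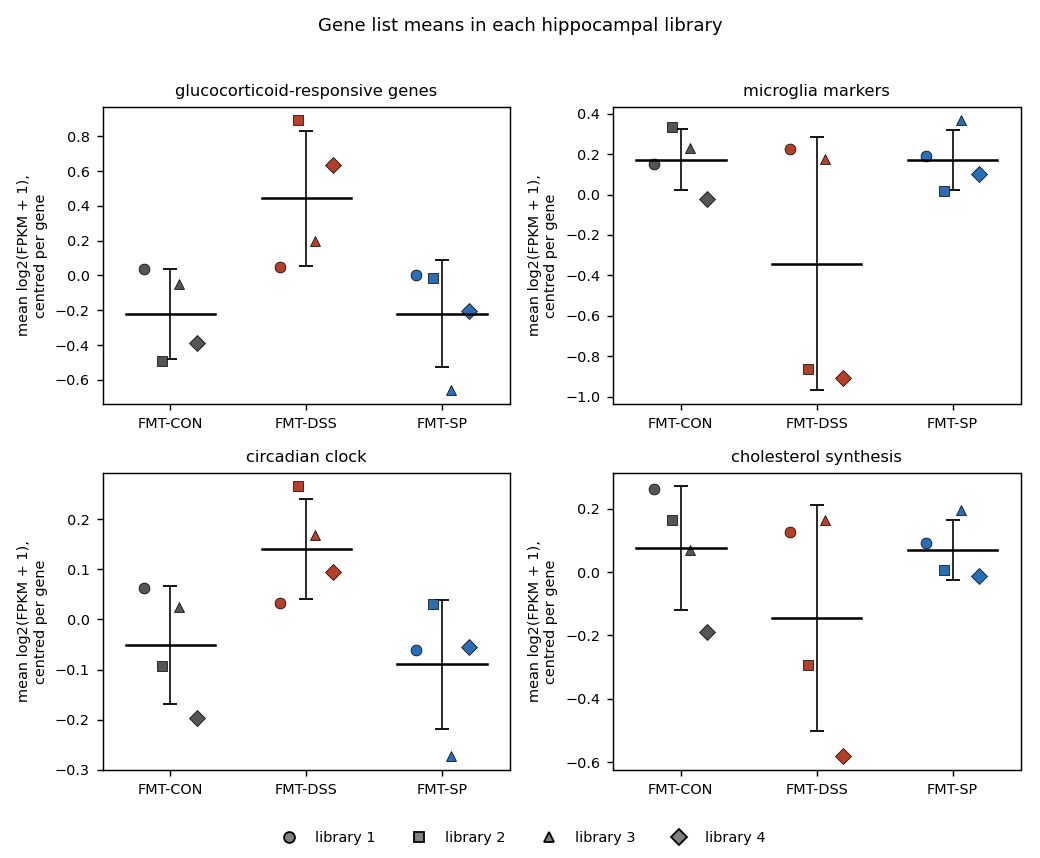
Mean of log2(FPKM + 1), centred per gene, over the glucocorticoid-responsive, microglia, circadian clock and cholesterol synthesis lists in each library (points, marked by library number), with the group mean and SD as bars, n = 4. The glucocorticoid means of FMT-DSS average 0.44, and those of FMT-CON and FMT-SP both -0.22.

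FMT-SP against FMT-CON asks how hippocampal gene levels of the group with substance P differed from those of FMT-CON. Glucocorticoid-responsive genes were 8 higher and 7 lower, with an adjusted p of 0.612 by camera. All 14 markers of oligodendrocytes and myelin had lower means in FMT-SP, by -0.32 on average, among them Mbp, a main protein of myelin, at 447 ± 123 FPKM against 586 ± 137 (SD, n = 4). Of 26 ribosomal proteins of the cytosol, 25 had lower means (-0.11 on average). Among synaptic genes, 15 of 16 for presynaptic release and 14 of 16 for postsynaptic scaffolds had higher means, by 0.11 on average in each list.

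Limma gave 0 of 12559 genes past the threshold, with a smallest adjusted p of 0.999995. There were 45 genes at an unadjusted p under 0.05 (8 higher, 37 lower, 628 by chance). That count was 14 without FMT-SP 1, 16 without FMT-SP 2, 81 without FMT-CON 4, 126 without FMT-SP 4, 138 without FMT-CON 2, 216 without FMT-SP 3 and 1146 with array weights. There were 62 genes with groups that did not overlap (0.494%, with 2.86% by chance). The gene of smallest p was Cystm1, on chromosome 18 (36342520 to 36403097), at 22.1 ± 2.24 FPKM in FMT-SP and 27.6 ± 1.61 in FMT-CON, a change of -0.31 ± 0.09. Tnfsf12, a member of the tumour necrosis factor family, had a change of -0.45, Brinp2 one of 0.25 and Ctxn3 one of -1.26. Serf1, Bphl, Apool and the long noncoding RNA Snhg18 had changes of -0.44, -0.29, -0.37 and -0.38, and BC064078 and AA465934 had 0.37 and 0.44. Of these 10, Cystm1 and BC064078 had groups that did not overlap.

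Camera called 15 of 45 lists, 6 higher and 9 lower in FMT-SP, and 0 passed with an estimated correlation or by fry. Each of the 15 had adjusted p = 0.617 with an estimated correlation. The ribosomal list had an adjusted p of 6.64e-06, with Rps27 at -0.26, Rps16 at -0.18 and Rplp2 at -0.15. Its average was -0.08 without FMT-CON 4 (adjusted p of 0.0758), -0.06 without FMT-CON 3 or FMT-SP 2, -0.18 without FMT-SP 4 and -0.07 with each library rescaled to a common sum. The myelin list had an adjusted p of 5.87e-05, with Mbp at -0.40, Mog at -0.36 and Mal at -0.29. It was lost without FMT-CON 1 (mean -0.12, adjusted p of 0.134), the library highest in thalamus markers, and without FMT-SP 4 (mean -0.19, adjusted p of 0.126), and its mean was -0.49 without FMT-CON 4 and -0.54 without FMT-SP 3.

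The postsynaptic scaffold genes (14 of 16 higher) had an adjusted p of 1.01e-04, with Camk2a at 0.29, Dlgap1 at 0.21 and Camk2b at 0.14. The presynaptic genes (15 of 16 higher) had 3.13e-04, with Syn2, Rims1 and Bsn at 0.20 and Cplx2 at 0.19. Both calls were lost without FMT-CON 1, at means of 0.05 and 0.07 and adjusted p of 0.185 and 0.195, and the postsynaptic mean was 0.18 without FMT-CON 2. They were also lost when the libraries highest in thalamus, striatum and pituitary markers were removed. Of 6 hypothalamus and pituitary markers, 5 had lower means (adjusted p of 2.29e-04), with Gh at -2.86, Prl at -2.30, Cga at -1.56 and Avp at -0.88. The mean of -1.35 for that list became -0.44 without FMT-CON 3, the library with 2899 FPKM of Gh.

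The other 10 lists called were each lost without at least 1 library. Lower in FMT-SP were nuclear oxidative phosphorylation (21 of 26 members, adjusted p of 3.13e-04, 0.146 without FMT-CON 4), ependymal markers (9 of 9, 0.00135, 0.277 without FMT-SP 4) and striatum markers (10 of 10, 0.00339, 0.323 without FMT-CON 2). The unfolded protein response (13 of 14, 0.00596) had 0.0734 without FMT-CON 2, thalamus markers (8 of 8, 0.00693) had 0.751 without FMT-CON 1, and meningeal markers (8 of 9, 0.0468) had 0.604 without FMT-SP 1. Higher in FMT-SP were markers of CA1 (6 of 8, 0.0140, 0.789 without FMT-CON 1), erythrocytes (5 of 5, 0.0272, 0.294 without FMT-CON 2) and interneurons (10 of 12, 0.0392, 0.668 without FMT-CON 1), and glutamate receptors (15 of 22, 0.0392, 0.216 without FMT-CON 3). The erythrocyte mean of 0.50 turned to -0.25 without FMT-SP 2 (adjusted p of 0.151), the library with Hbb-bs at 682 FPKM. Without FMT-CON 1, the mean turned to -0.02 for CA1 and to 0.02 for thalamus markers. The other 30 lists had adjusted p between 0.0526 and 0.983. Mean, median and test differed in sign for microglia activation, cholesterol synthesis, nuclear-retained long noncoding RNAs, microglia, oligodendrocyte precursor, pericyte and dentate granule cell markers.

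The genes of the substance P system showed no change past the test in any comparison. Tac1, the precursor gene of substance P on chromosome 6 (7554879 to 7565834), was at 9.84 ± 3.56 FPKM in FMT-CON, 12.01 ± 10.2 in FMT-DSS and 7.18 ± 1.87 in FMT-SP (n = 4). The exact permutation p of Tac1 was 0.971, 0.486 and 0.286 for FMT-DSS against FMT-CON, FMT-SP against FMT-DSS and FMT-SP against FMT-CON. Tac2, the neurokinin B gene on chromosome 10 (127724478 to 127731768), was at 16.5 ± 23.7, 10.2 ± 9.78 and 7.71 ± 4.13 FPKM, with exact permutation p of 0.829, 0.829 and 0.914. Tacr1, the receptor of substance P, was below the filter at 0.732, 0.543 and 0.457 FPKM. Tac1 was highest in FMT-DSS 3 (26.7 FPKM), the library highest in striatum markers. Tac2 (51.9 FPKM) and Tacr1 (1.84 FPKM) were highest in FMT-CON 1, the library highest in thalamus markers. Tac4, Tacr2 and Tacr3 were also below it, so the tachykinin list, with 3 tested genes, was too small for a list test at that filter; at a mean of 0.1 FPKM it had 5 and adjusted p of 0.782, 0.590 and 0.296. Its member Mme, a peptidase that degrades substance P, was at 1.09, 1.18 and 0.928 FPKM.

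Most inflammatory cytokine genes were below the filter of 1 FPKM. Cxcl1 and Cxcl10, chemokine genes, had their highest means in FMT-DSS: Cxcl1 was at 0.152 ± 0.210, 1.47 ± 2.31 and 0.144 ± 0.0983 FPKM in FMT-CON, FMT-DSS and FMT-SP, and Cxcl10 at 0.132 ± 0.0845, 0.802 ± 1.09 and 0.132 ± 0.104. The exact permutation p for FMT-DSS against FMT-CON was 0.257 for Cxcl1 and 0.0571 for Cxcl10. Ccl2 was at 0.0944 ± 0.0702, 0.578 ± 1.11 and 0.0685 ± 0.091 FPKM and Ccl3 at 0.481 ± 0.391, 0.572 ± 0.405 and 0.279 ± 0.155. Their exact permutation p for FMT-DSS against FMT-CON was 0.943 and 0.657. Il1b was at 0.105, 0.0926 and 0.0749 FPKM in FMT-CON, FMT-DSS and FMT-SP, and Tnf and Il6 were lower still. Il18 (11.1, 10.6 and 10.3 FPKM) and Ptgs2 (4.43, 4.66 and 5.23 FPKM) were the 2 tested members, too few for a list test at that filter. At a mean of 0.1 FPKM, 8 cytokine genes were tested, with adjusted p of 0.164 for FMT-DSS against FMT-CON (5 higher, 3 lower), 0.0588 for FMT-SP against FMT-DSS (1 higher, 7 lower) and 0.867 for FMT-SP against FMT-CON. The peripheral leukocyte list also had 2 tested members, or 5 at 0.1 FPKM with adjusted p of 0.201, 0.146 and 0.939. Its member Cd4, a marker of helper T cells, was at 0.466 ± 0.417, 1.13 ± 1.53 and 0.134 ± 0.147 FPKM, with exact permutation p of 0.543, 0.400 and 0.200. The T cell genes Cd3e (0.0045, 0.0092 and 0.009 FPKM) and Cd8a (0.0181, 0 and 0.0088 FPKM) were near 0, so Cd4 gives no evidence of T cells here. Of the 45 lists at the filter of 1 FPKM, 16 passed in no comparison, with adjusted p between 0.0526 and 0.983: NF-kB targets, interferon-stimulated genes, microglia activation, monoamine receptors, heat shock, tight junctions, tryptophan metabolism, antioxidant genes, apoptosis, nuclear-retained long noncoding RNAs, and markers of astrocytes, oligodendrocyte precursors, endothelium, pericytes, CA3 and neocortex.

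The NF-kB list changed with the filter. At 1 FPKM, 5 of its 13 genes were tested; at 0.1 FPKM all 13 were, and camera called the list higher in FMT-DSS than in FMT-CON (0.29 on average, 8 higher and 5 lower, adjusted p of 1.18e-05) and lower in FMT-SP than in FMT-DSS (-0.29, 4 higher and 9 lower, adjusted p of 2.57e-06). With no filter the adjusted p were 9.21e-05 and 3.45e-05. Camera kept both calls at 0.1 FPKM without any 1 library (highest adjusted p of 0.00136 without FMT-CON 4 and 6.33e-04 without FMT-SP 4), and without both FMT-DSS 2 and FMT-DSS 4 (means 0.16 and -0.16, adjusted p of 0.01003 and 0.00380). With an estimated correlation the adjusted p were 0.178 and 0.190, by fry 0.354 and 0.386, and the exact permutation p of the list mean was 0.114 and 0.0571. In FMT-SP against FMT-CON the adjusted p was 0.939. Nfkb2 was at 0.160 ± 0.0493, 0.458 ± 0.239 and 0.152 ± 0.0618 FPKM in FMT-CON, FMT-DSS and FMT-SP, Relb at 0.544 ± 0.0732, 0.936 ± 0.166 and 0.505 ± 0.0976, and Ikbke at 0.444 ± 0.194, 1.28 ± 0.444 and 0.401 ± 0.157. These 3 genes, picked after their values were seen, had an exact permutation p of 0.0286, the smallest possible, in both FMT-DSS comparisons. Adjusted over the list alone, 5 members passed in FMT-DSS against FMT-CON and 3 in FMT-SP against FMT-DSS, those 3 genes in both; over all genes, 0 passed. The count of 5 was 2, Relb and Ikbke, without FMT-CON 1, FMT-CON 4 or FMT-DSS 2, and 3 without FMT-CON 3, FMT-DSS 4 or any FMT-SP library. The count of 3 was 6 without FMT-DSS 1 and 2, again Relb and Ikbke, without FMT-SP 2 or FMT-SP 4. Without both FMT-DSS 2 and FMT-DSS 4, Nfkb2 and Ikbke passed in each comparison. Interferon-stimulated genes passed in FMT-SP against FMT-DSS with no filter only (18 higher and 4 lower, adjusted p of 0.0433), and not with an estimated correlation (0.759) or by fry (0.822). That call was lost without FMT-DSS 1, FMT-DSS 4, FMT-SP 3 or FMT-SP 4 (0.382 without the last).

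Whether FMT-SP reversed the FMT-DSS values was tested across genes. By limma, 0 genes were called in opposite directions in FMT-DSS against FMT-CON and FMT-SP against FMT-DSS, which decides nothing, as neither had a called gene. At an unadjusted p under 0.05 in both, 138 genes moved in opposite directions, 64 higher then lower and 74 lower then higher, and 0 moved in the same direction. Simulated data with no group effect gave 143.3 such genes on average, because the comparisons share the FMT-DSS libraries. Simulated genes were independent, where chance gives 628 genes per comparison, while the real comparisons had 510 and 314. The 138 and 143.3 genes therefore come from unlike totals and do not decide the question. From the real totals, comparisons without shared libraries would give 6.41 such genes. Camk1, Grm2, Klf15 and Pdk4 were among the genes of smallest p or the list members named in both comparisons. The correlation of fold changes across genes, which are not independent replicates, was -0.77 with shared libraries, against -0.50 in the simulations and -0.84 to 0.05 in relabelled libraries (median -0.53), of which 15 of 100 were at or below the observed value. With the FMT-DSS libraries split between the comparisons it averaged -0.06 over the 6 splits (-0.33 to 0.12), and relabelled libraries gave -0.52 to 0.42. Without FMT-DSS 2 and FMT-DSS 4 it was 0.07. Leaving out 1 library gave between -0.14 (without FMT-DSS 1) and 0.16 (without FMT-DSS 2).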

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

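Chosen only after results were seen were the tests of neighbouring tissue as a source of marker differences, of library scaling, of gene counts over other splits, the tissue covariates and the contrast of FMT-DSS with the other 8 libraries.

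In 17 of 257 checks (6.61%) of a reported gene or a described list within a group of 4, the highest or lowest library lay so far from the nearest other that the gap took more than 0.829 of the whole range, and chance gives about 1 in 20. FMT-CON 3 was far above its group in Gh (gap share 0.902), Prl (0.891), Cga (0.935) and the hypothalamus and pituitary list mean (0.883). FMT-CON 1 was high in Camk1 (0.879) and Tac2 (0.892). FMT-CON 2 was low in Fkbp5 (0.950) and Pigbos1 (0.851). FMT-DSS 1 was low in Chia1 (0.976) and Ddit4 (0.889), and FMT-DSS 2 was high in Cry2 (0.916) and Fibcd1 (0.862). FMT-DSS 4 was low in Ikbkg (0.915) and Syn2 (0.865). FMT-SP 3 was high in Ppp1r1b (0.852), low in the CA1 list mean (0.857) and alone above 0 in Cga within FMT-SP (gap share of 1).

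Glucocorticoid-responsive genes were higher in FMT-DSS than in the other 8 libraries, by 0.66 (95% interval 0.25 to 1.08), with all 4 list means (0.05, 0.89, 0.20 and 0.63) above the highest of the others, 0.04 in FMT-CON 1, and the larger ones in FMT-DSS 2 and FMT-DSS 4, which were also low in microglia markers. The exact permutation p of this contrast was 0.00202, the smallest that 495 assignments can give, on a contrast picked from the same data. Adjusting for choroid plexus and striatum marker means left 0.74 (0.34 to 1.15), 1.12 times the unadjusted difference, which argues against those tissues as the whole cause. A different time of day at collection stays open: the difference of the clock arms, 7 genes against 4, was 0.30 (-0.08 to 0.68), an interval that reaches both 0 and the list's own 0.66. The transplant itself, and handling or stress at collection, remain as hypotheses that these data could not separate.

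Markers of neighbouring tissue differed strongly between libraries of one group. Within groups, the lowest mean correlation between members of the choroid plexus, ependymal, striatum and thalamus lists was 0.914. Differing amounts of neighbouring tissue in the dissected samples would give such values. Erythrocyte markers had 0.968, but hypothalamus and pituitary markers had 0.258 and meningeal markers 0.406, with lowest pairs of -0.454 and -0.337. These correlations therefore do not show that account for the hypothalamus, pituitary and meningeal markers. The hypothalamus and pituitary list pools both tissues, and its pituitary hormone genes Gh, Prl and Cga were all far above their group in FMT-CON 3. Its low correlation thus does not speak against pituitary tissue in that library. Library scaling is argued against, since Ttr differed by 131 times within FMT-CON where scaling factors differed by at most 1.13 times. No biological explanation was tested, and real regional changes within an animal remain open.

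The 8 named genes lower in FMT-DSS than in FMT-CON had a median change of -0.45. Correcting each library for its trend with transcript length left -0.39, a ratio of 0.865, and correcting for GC content left -0.42, a ratio of 0.944. Since the largest shift of any of the 12271 genes (97.7%) with values was 0.15 and 0.10, such trends were too small to be the whole cause, and a part is not excluded. None of the 8 passed the test over all genes, so a sampling effect and the transplant both remain open.

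Chance could not be excluded for the counts of lists over the 35 splits of the 8 libraries of a comparison into 4 and 4. As many or more came from 23 splits in FMT-DSS against FMT-CON (11 in the real split, 22 at most in another), from 5 in FMT-SP against FMT-DSS (18 and 24) and from 11 in FMT-SP against FMT-CON (15 and 17). For genes called the real count was 0, so all 35 splits had to give as many in each comparison and the count decides nothing. The highest other splits gave 14, 0 and 58. Counts at an unadjusted p under 0.05 were as large as the real 510, 314 and 45 in 18, 21 and 28 of the 35 splits, the real one included. The highest other splits gave 3885, 2432 and 2989 such genes, so the 628 by chance is an average and not a bound.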

How the results depend on the processing

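The tissue covariates, the removals of more than 1 library and the exact permutation counts were chosen after the data were seen. The count of genes past the threshold was 0 in all 3 comparisons under every setting and every left-out library (range 0 to 0), except for 14 in FMT-SP against FMT-DSS with choroid plexus and striatum covariates; the cause was not tested. Counts of lists (11, 18 and 15 by camera) were 0, 0 and 0 with an estimated correlation, 0, 0 and 0 by fry, and 2, 3 and 0 at an unadjusted exact permutation p, since these use the correlation between genes or the spread between libraries. Leaving out 1 library gave 10 to 17, 6 to 18 and 8 to 19 lists. In FMT-SP against FMT-DSS, the covariates gave 11 lists and removing the libraries highest in thalamus, striatum and pituitary markers gave 9. Without FMT-DSS 2 and FMT-DSS 4, 14, 13 and 13 lists were called, and 3, 6 and 13 of them are among the lists called with all libraries. With the replicate block, 0 genes passed in each comparison and 9, 13 and 13 lists did; unadjusted counts were 1274 (381 higher, 893 lower), 885 (570 higher, 315 lower) and 310 against 510, 314 and 45 without it, where chance gives 628. Without the block, other splits of the libraries gave up to 3885, 2432 and 2989 genes at that p, and splits with the block were not run. Replicate numbers are not shown to pair samples across the design: 9 of 12 same-numbered pairs correlated above 0.1, over a range of -0.451 to 0.841, and 7 of 12 libraries were closest to their own number. Between FMT-DSS and FMT-SP alone, all 4 pairs lay above 0.1 (0.108 to 0.694). Pairs among the libraries numbered 4 were at 0.694 to 0.841. The libraries numbered 4 therefore shared a structure, and one for the other numbers is not excluded. The main model leaves both in the spread, so its unadjusted counts of 510, 314 and 45 carry them. The correlation of fold changes with split FMT-DSS libraries, -0.0646, ranged from -0.144 to 0.155 on leaving out 1 library, was above 0 without FMT-DSS 2 (0.155), FMT-DSS 4 (0.0077) and FMT-SP 3 (0.0118), and was 0.0871 without the 3 libraries numbered 4. Genes in opposite directions were 0 throughout (range 0 to 0), which decides nothing, since no gene was called in FMT-DSS against FMT-CON under any setting. Of 2310 values of named genes under alternatives, 2284 kept direction and side of the threshold, 1 passed it (Tmem119 with covariates) and 25 turned, none of them called. Much of that count was fixed in advance. No named gene was called in the main fit, and some settings, such as robust empirical Bayes, leave the change itself as it was. Tac1 in FMT-DSS against FMT-CON turned with a pseudocount of 0.1 (-0.00567), without FMT-CON 3 (-0.163), FMT-CON 4 (-0.0657), FMT-DSS 1 (-0.0618) or FMT-DSS 3 (-0.451), with covariates (-0.0979) and with the tissue-high libraries removed (-0.447), over -0.451 to 0.340, where each such range is over left-out libraries. Tac1 in FMT-SP against FMT-DSS turned without FMT-DSS 3 (0.0749), with covariates (0.0931) and with that removal (0.0749), over -0.716 to 0.0749. Tac2 in FMT-DSS against FMT-CON turned without FMT-CON 1 (0.645) or FMT-DSS 1 (0.179) and with that removal (0.763), over -0.682 to 0.645. Tac2 in FMT-SP against FMT-DSS turned without FMT-DSS 2 (0.404), FMT-SP 1 (0.0266) or FMT-SP 2 (0.0327) with covariates (0.208) and without FMT-DSS 2 and FMT-DSS 4 (0.465), over -0.457 to 0.404, and in FMT-SP against FMT-CON without FMT-CON 1 (0.532) and with the removal (0.609), over -0.622 to 0.532. Without FMT-DSS 2 and FMT-DSS 4, Siglech (-0.0156), P2ry13 (-0.0312), Sqle (-0.00992), Hmgcs1 (-0.0294) and Dhcr7 (-0.0126) turned in FMT-SP against FMT-DSS. Of 1228 list values, 880 kept direction and call, 324 lost the call and 24 turned. Without those libraries, lists that turned in FMT-DSS against FMT-CON were reactive astrocyte genes (-0.213), the unfolded protein response (0.0145), cholesterol synthesis (0.0684) and microglia markers (0.0285). In FMT-SP against FMT-DSS they were antigen presentation (0.0516), complement (0.0494), reactive astrocyte genes (0.0597), mitochondrially encoded genes (0.0833), ribosomal proteins (0.0192), cholesterol synthesis (-0.0741), microglia markers (-0.0314) and, by camera's direction only, erythrocyte markers (-0.0434, with all libraries -0.564). In FMT-DSS against FMT-CON, reactive astrocyte genes turned with array weights (-0.0735) and without FMT-DSS 2 (-0.0159, over -0.0159 to 0.573). In FMT-SP against FMT-DSS, complement turned without FMT-DSS 2 (0.0607, over -0.255 to 0.0607), mitochondrially encoded genes without FMT-DSS 4 (0.0144, over -0.310 to 0.0144), ribosomal proteins without FMT-DSS 4 (0.00748, over -0.135 to 0.00748) or FMT-SP 2 (0.00279) and ependymal markers with covariates (0.0867). In FMT-SP against FMT-CON, CA1 markers turned without FMT-CON 1 (-0.0229, over -0.0229 to 0.286) and, by camera, with the removal (0.00292), thalamus markers without FMT-CON 1 (0.0247, over -1.13 to 0.0247), erythrocyte markers without FMT-SP 2 (-0.255, over -0.255 to 0.908) and meningeal markers with the removal (0.00796). Fewer libraries explain part of the lost calls by construction; beyond that the cause was not tested. The choroid plexus and striatum lists have no value with covariates made from them. No called list turned under the 3 rescalings. Genes with a mean of 0.1 to 1 FPKM, some cytokines among them, entered the model at a filter of 0.1 FPKM. Those under 0.1 FPKM, such as Il1b, Tnf and Il6, entered only with no filter. In both settings 0 genes passed in each comparison.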

Other observations

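The tissue covariates, the fit with them and the genes named here were chosen after results were seen.

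Within FMT-DSS, replicates 2 and 4 differed from 1 and 3 in microglial genes that the groups alone do not describe. P2ry12, a purine receptor of resting microglia, was at 2.66 and 3.20 FPKM in FMT-DSS 2 and FMT-DSS 4, and Tmem119, a microglial membrane protein, at 2.83 and 3.13. Csf1r, the growth factor receptor of microglia, was at 19.1 and 9.15 FPKM in the same libraries, and averaged 16.8 in FMT-CON and 18.8 in FMT-SP. Cga, a subunit shared by pituitary hormones, was listed at 0 in all 4 FMT-DSS libraries and at 49.8 FPKM in FMT-CON 3.

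With choroid plexus and striatum marker means as covariates, limma called 14 genes in FMT-SP against FMT-DSS, 12 higher and 2 lower. The lower ones were Icam1, an adhesion molecule of inflamed endothelium (-1.46), and Apod, a lipid carrier (-1.07); the higher ones included Tmem119 (0.73), the endothelial receptor gene Tek and Trib2. Chance could not be excluded: 2 of 35 splits, the real one included, gave as many genes, with 14 in the real split and 1102 in the highest other. No remaining split gave any gene. A split with as many as 1102 points to a structure of the samples. That split set FMT-DSS 1, FMT-DSS 2, FMT-SP 1 and FMT-SP 2 apart from the rest, so numbers 1 and 2 from numbers 3 and 4. Genes at an unadjusted p under 0.05 with the covariates were 1745 in FMT-DSS against FMT-CON, 2236 in FMT-SP against FMT-DSS and 132 in FMT-SP against FMT-CON. Chance gives 628 on average. Other splits of the same libraries were counted at that p without covariates only, and gave up to 3885, 2432 and 2989 such genes. They are no reference for counts with covariates. With no matching reference, counts above 628 do not decide on a group effect.

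The axis of largest variance between libraries held 42.7% of the variance, and 2.84% of it lay between groups. It set FMT-CON 4, FMT-DSS 4 and FMT-SP 4 (27.9, 37.2 and 23.1) apart from the other libraries (-20.7 to 7.25). Over the lists, its correlation with the list mean was highest for mitochondrially encoded genes (0.93) and lowest for astrocyte markers (-0.95). The next axis held 19.3%, with 34.99% between groups, where 18.2% is expected without any group effect. That axis was carried by FMT-DSS 2 (-34.9) and FMT-DSS 4 (-16.6), while FMT-DSS 1 and FMT-DSS 3 (1.21 and 7.84) lay among the other groups (-2.74 to 11.99).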
